A study of Mus musculus with 2 samples.

How the data were processed

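Tle3 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in lineage-negative, cKit-positive bone marrow cells of wild-type C57BL/6 mice aged 8 to 10 weeks. The data comprised 2 libraries, 1 made with an antibody against Tle3 and 1 control. The control was labelled normal IgG in its title and antibody field and input in its source name and description, so the kind of control was not settled; it is called the control library here. Some label fields call the cells T cells, while the cell type field calls them hematopoietic progenitors. Per the labels' protocols, fixed and sonicated chromatin was immunoprecipitated, and the libraries were amplified for 18 to 21 PCR cycles and sequenced on an Illumina HiSeq instrument.

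Per the submitters' processing notes, Bowtie2 and MACS 1.4 were used with the mouse build mm9. The parameters, read filters and treatment of duplicate reads are not given in the sources used here. The deposited file was 1 list of called regions (peaks), each with a chromosome, a start, an end, a running number and a score. The score deposited by the authors is the MACS score of each peak, in MACS 1.4 the negative log10 of the p-value of the peak against the local background, multiplied by 10. It is neither a read count nor a fold enrichment, it rises with sequencing depth, and it was used only to describe, rank and filter peaks within the list. Its minimum of 50 corresponds to a p-value of 1e-05. The running numbers had 0 gaps and 0 peaks overlapped, which does not show whether peaks were filtered before they were numbered. The file gave no summits, no read counts and no library totals, so the sequencing depth of both libraries is unknown, and no limits of detection were computed. With 1 library per antibody there was no replicate check, and every p-value below describes this list against random placement or permutation, not the spread between animals.

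Starts were converted from the BED convention to positions counted from 1, and all positions are in mm9 as named by the submitters. Distances between peaks were measured from edge to edge. For clustering, the share of peaks with another peak within 10 kb was compared with 1000 sets in which the peaks of each chromosome were placed uniformly between its first and last peak, one-sided. Score and width were compared across peaks with Spearman's rho and Pearson's r and 100000 permutations, two-sided. Shares carry 95% exact (Clopper-Pearson) intervals that cover counting error only, and neighbouring peaks are not independent. The number of peaks per chromosome was planned as counts only, because mm9 chromosome lengths were not used here. A two-sided exact binomial test against the span between the first and last peak of each chromosome, with Benjamini-Hochberg adjustment over 20 chromosomes, was added after the data were seen. It was repeated over the 19 autosomes alone. The clustering test was tested on simulated lists of 5136 peaks, with fewer than 1000 placements per list. It called 1 of 20 lists without clustering and 10 of 10 lists in which 5% of peaks had been set beside another. The lists without clustering were drawn by the same uniform placement as the random sets. The simulation therefore does not cover assembly gaps or uneven gene density.

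The gene table at hand was that of GRCm38.p6, another build than mm9. As a planned check, the share of peak midpoints within 1 kb of either end of its 21627 protein-coding genes was computed, since the table gives no strand. This share was 8.18% (7.44 to 8.96%) for the peaks as listed, 5.33% (4.74 to 5.99%) after a shift of 1 Mb and 3.64% (3.15 to 4.19%) after a shift of 5 Mb. On chromosome 16 alone it was 40.6%, and on the other chromosomes it lay between 1.31% and 13.4%. A missing enrichment was to be read as another build, but the unshifted share lay above both shifted ones. The check alone therefore did not show another build. Without chromosome 16 the unshifted share was 7.07% (6.37 to 7.82%). Shifts of 20 kb either way, added after the data were seen, gave 6.10% (5.45 to 6.80%) and 5.88% (5.24 to 6.57%). These intervals overlap, so outside chromosome 16 the check did not show a match to the table's build either. Because the submitters name mm9, the list was treated as lying on another build than the table. The table's coordinates were used only in this check and its later extension by chromosome and by shifts of 20 kb. No peak was assigned to a gene. Gene lists, DNA motifs, promoter distances and gene features fixed before the data were examined were not analysed here for the same reason. Under the rule fixed in advance for this case, the 15 highest scoring and the 5 widest peaks are named by position, and no gene is named. The alternatives were a score of at least 100, merging of peaks within 1 kb, a neighbour distance of 50 kb and a 5 kb window in the build check, with further settings added later. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.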

Results

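Binding of Tle3 across the genome was mapped in bone marrow progenitor cells, selected for absence of lineage markers and presence of cKit, the receptor for stem cell factor. Tle3 belongs to the Groucho family of transcriptional corepressors, which have no DNA-binding domain of their own and are brought to chromatin by factors such as RUNX, TCF/LEF and HES proteins. The comparison was between 1 Tle3 library and 1 control library, without replicates. It asked which regions were enriched by the Tle3 antibody. The peak list made by the authors held 5136 peaks on 20 chromosomes (1 to 19 and X). No read totals accompany it, so the depth behind each peak is unknown.

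Most Tle3 peaks were narrow and scored under 100, and a small number stood far above the rest. The peaks covered 3.69 Mb in all. Their median width was 657 bp, with quartiles of 533 and 823 bp, and 572 peaks (11.1%) were wider than 1000 bp. The median score was 68.82, with quartiles of 56.7 and 99.2 on a scale that starts at 50. A score of at least 60 was reached by 3417 peaks, or 66.5% (95% exact interval 65.2 to 67.8%). A score of at least 100 was reached by 1258 peaks (24.5%, 23.3 to 25.7%). A score of at least 200 was reached by 226 peaks (4.40%), and a score of at least 400 by 26 peaks. Only 3 peaks scored 1000 or more.

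The highest score, 3100, belonged to a peak of 3852 bp on chromosome 17 (39979935 to 39983786). Whether 3100 is a measured score or the numerical ceiling of the caller's scale is not known, and whether this region is multi-copy sequence, where reads of several copies pile up, was not examined. A second peak lay 563 bp downstream of it (39984350 to 39985860), with a score of 687. Multi-copy sequence was not examined for this second peak either. The second highest score was 1113, on chromosome 15 (7166536 to 7167613), and the third was 1042, on chromosome 7 (19661251 to 19663850). A further peak on chromosome 7, at 19901597 to 19902370, scored 582 and had a neighbour 2704 bp away. On chromosome 3, the peak at 30992522 to 30994659 scored 680 and was 2138 bp wide. The peaks at 114344857 to 114345768 on chromosome 8 and at 108872634 to 108873594 on chromosome 11 scored 617 and 600, and the nearest other peaks were 167172 and 413487 bp away. Chromosome 6 carried 2 of the 15 highest scoring peaks, at 113256360 to 113257283 (score 537) and at 94710462 to 94711525 (score 498). The latter was the most isolated of the 15, at 572670 bp from the next peak. The remaining 5 scored between 494 and 526. They lay on chromosome 17 (31972210 to 31973370), chromosome 18 (55059451 to 55060535), chromosome 15 (103088470 to 103089501), chromosome 1 (166065261 to 166066453) and chromosome 7 (86610361 to 86611595).

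The widest peaks were in part different from the strongest ones. The widest of all, 6288 bp, lay on chromosome 1 (90140986 to 90147273) and scored 97.85, higher than 74.4% of the peaks. Its next neighbour, 24980 bp downstream (90172254 to 90175260), was 3007 bp wide and scored 67.64, below the median score. On chromosome X, near the last position with a peak, the peaks at 166429578 to 166433244 and 166443198 to 166446328 were 3667 and 3131 bp wide and scored 96.21 and 86.58. Multi-copy sequence was not examined for any peak named here, including these wide regions on chromosomes 1 and X. All named peaks are therefore called regions and not established Tle3 sites. The peak of 3852 bp on chromosome 17 was the only one among both the 5 widest and the 15 highest scoring. Across all peaks, score rose with width. Spearman's rho was 0.74 and Pearson's r was 0.59 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Among the 1258 peaks scoring at least 100, rho was 0.46 and r was 0.47. This subset is cut on score itself, which alone can lower a correlation. The lower values therefore do not show a weaker relation among high-scoring peaks. The median score was 54.85 among peaks up to the lower quartile of width and 122.8 among those above the upper quartile. Peaks are not independent replicates, and both values come from the same caller, so this relation describes the list.

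Chromosome 11 held the most Tle3 peaks, 439, and chromosome X the fewest, 40. Per megabase between the first and last peak, chromosome 11 had 3.72 peaks (95% interval 3.39 to 4.07). Chromosomes 19 and 17 followed with 3.21 (2.77 to 3.69) and 3.13 (2.77 to 3.51). The sparsest autosomes were chromosome 14 with 1.35 (1.14 to 1.57), chromosome 18 with 1.43 (1.19 to 1.70) and chromosome 3 with 1.48 (1.29 to 1.68). Chromosome X had 0.251 peaks per megabase (0.180 to 0.342), against 2.15 over the 19 autosomes, a difference of 8.57-fold (6.30 to 12.0). Chromosome X held 0.779% of all peaks (0.557 to 1.06%) and 9 of the 1258 peaks with a score of at least 100 (0.715%). In the exact binomial test against span, added after the data were seen, 8 chromosomes held more peaks and 7 fewer than their span gave, at an adjusted p under 0.05. The low count on X raises the ratio of every autosome in that test. Among the 19 autosomes alone, 4 held more (5, 11, 17 and 19) and 7 fewer (1, 3, 12, 13, 14, 16 and 18). The adjusted p over all 20 chromosomes was 1.9e-31 for chromosome 11 and 1.3e-90 for chromosome X. The test treats peaks as independent, which the clustering described next contradicts, so these p-values are too small.

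**Figure D1:**
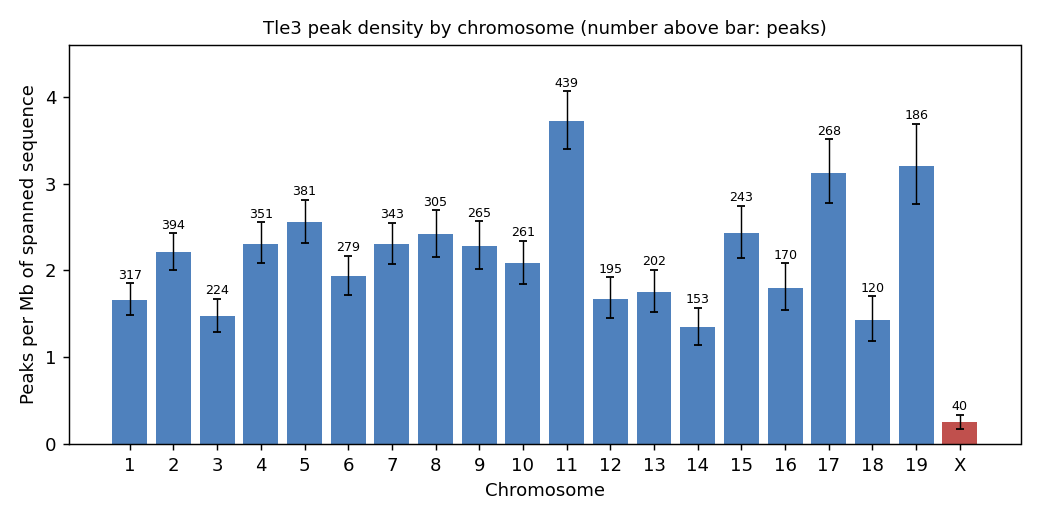
Tle3 peaks per megabase of the span between the first and last peak of each chromosome, with the number of peaks above each bar; error bars are 95% exact binomial intervals for counting error. Chromosome 11 is highest at 3.72 and chromosome X lowest at 0.251 peaks per megabase.

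The X-linked peaks that were called did not stand apart in score. Their median was 64.9, against 68.9 on the autosomes, a difference of -3.97 (two-sided permutation test, 40 against 5096 peaks, p = 0.446). The strongest peak on X scored 317. On chromosome X, 7 of the 40 peaks lay in the 1 megabase from 71000001 to 72000000. Downstream of them came the longest interval without a peak, 27.3 Mb from 71558654 to 98835044. The next longest were also on X, at 18.99 Mb (20509595 to 39502961) and 16.8 Mb (54307058 to 71069678). The longest on an autosome was 12.4 Mb, on chromosome 15 (12795887 to 25157229). Assembly gaps and sequence that reads cannot be placed on were not examined here.

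Tle3 peaks lay in dense stretches separated by long empty ones. In tiles of 1 Mb, the fullest held 26 peaks, on chromosome 10 from 79000001 to 80000000, and the tile after it held 21. The tile from 167000001 to 168000000 on chromosome 2 also held 21. There were 20 peaks each in the tiles from 120000001 to 121000000 on chromosome 11 and from 34000001 to 35000000 on chromosome 17. The peaks of these tiles had ordinary scores, with medians between 64.0 and 75.46. Over 1000 uniform placements of the same number of peaks, the fullest tile held 16. In the list, 9 tiles held more than 16, with 179 peaks (3.49%) in all. No peak fell in 1125 of 2547 tiles (44.2%), against 410 to 488 empty tiles in the random placements (one-sided permutation test by random placement, p = 0.001, the smallest that 1000 placements can give). These tiles were examined after the data were seen. The placements did not leave out assembly gaps or sequence that reads cannot be placed on, which may account for part of the empty tiles.

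**Figure D2:**
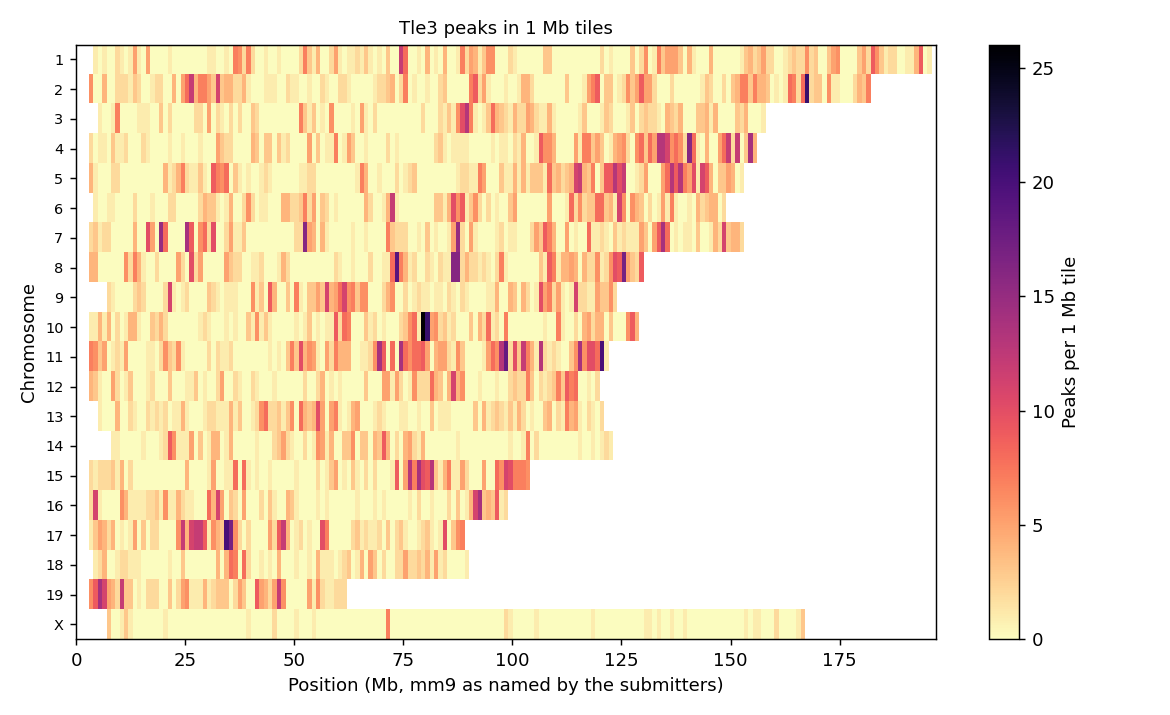
Number of Tle3 peaks in each 1 Mb tile (colour) along each chromosome, in megabases of mm9; white lies outside the span between the first and last peak. The darkest tile, on chromosome 10 from 79000001, holds 26 peaks, and chromosome X is nearly empty.

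At shorter range, 1140 of 5136 peaks (22.2%, 21.1 to 23.4%) had another peak within 10 kb. Uniform placement gave 4.76% on average and at most 6.07% in 1000 sets, so the observed share was 4.66 times the random mean (one-sided permutation test by random placement, p = 0.001, the smallest possible). The ratio was 2.05 when each peak was placed within its own 1 Mb tile, which gave 10.8% on average, and 3.56 after merging peaks within 1 kb, both settings added after the data were seen. Within 50 kb, 49.5% of peaks had a neighbour, against 20.5% on average and at most 23.0% at random. Among the 1258 peaks scoring at least 100, 8.74% (7.24 to 10.4%) had another such peak within 10 kb, against 1.24% on average and at most 2.94% at random. The random placements did not leave out assembly gaps or sequence that reads cannot be placed on. This can lower the random shares and raise the ratios. Chaining peaks within 10 kb of each other gave 409 pairs, 80 groups of 3, 18 groups of 4 and 2 groups of 5, and left 3996 single peaks. The groups of 5 lay on chromosome 8 (125222769 to 125244821, scores 50 to 136) and on chromosome 5 (123576086 to 123601536, scores 54.94 to 105). The shortest group of 4 took up 6.61 kb on chromosome 5 (143578692 to 143585302). A group of 4 on chromosome 4 (135728614 to 135736403) held a peak scoring 342.5. These groups were chosen after their values were seen.

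**Figure D3:**
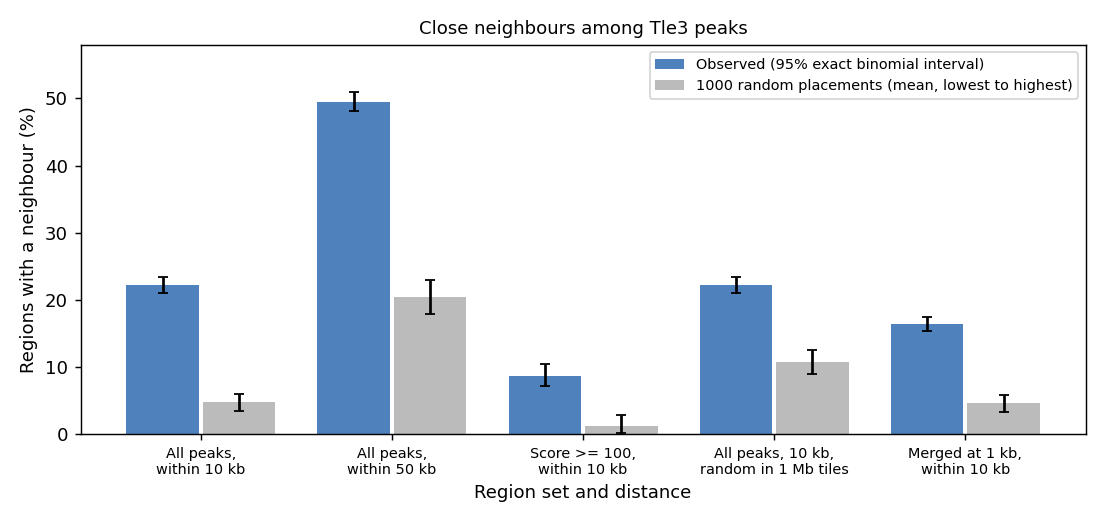
Percent of regions with another region within 10 or 50 kb, observed (blue, 95% exact binomial intervals) and over 1000 random placements (grey, mean with lowest and highest). In each of the 5 settings the observed share, such as 22.2% for all peaks within 10 kb, lies above the highest random one.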

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

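Some alternatives were added after the data were seen: merging and 1 Mb tiles for clustering, leaving out the 15 highest scoring and 5 widest peaks, leaving out chromosome 16 in the build check, and the span of each chromosome, with and without X. Leaving out X lowered the number of chromosomes with more peaks than their span gave from 8 to 4. A minimum score of 100 lowered the number of peaks from 5136 to 1258. Merging peaks within 1 kb left 4947, and restriction to chromosomes 1 to 19 and X removed none. Spearman's rho between score and width was 0.46 at a score of at least 100 and 0.74 without the highest scoring and widest peaks. Both had a permutation p of 1e-05. Cutting the list on score can by itself lower rho. Without the highest scoring and widest peaks Pearson's r was 0.70, against 0.59 for all peaks. The share of peaks on X was 0.779% overall and 0.715% at a score of at least 100. The share with a close neighbour exceeded the highest of 1000 random placements in each setting tried, with observed values from 8.74% to 49.5%. The share of peaks near gene ends of the other build was 25.2% in a 5 kb window. After shifts of 1 Mb and 5 Mb it was 18.9% and 14.5% in that window. In a 1 kb window without chromosome 16 the unshifted share was 7.07%, against 8.18% with it. Other settings for promoter share, gene features, motifs, gene lists, bound genes, the score of promoter peaks and placement over gene starts were not run, since no annotation of mm9 was used here. The list has no read totals, so how many weaker sites fell under the score of 50 for lack of depth cannot be given. No paired analysis was possible because there was 1 library per antibody.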

Other observations

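All tests in this part were chosen after the peak list had been seen, those of the single X copy and of chromosome 16 after their own results were in part seen. Peak number per autosome went with the number of protein-coding genes in the GRCm38.p6 gene table, which was used for counts of genes per chromosome, without coordinates. Over the 19 autosomes Spearman's rho was 0.93 (permutation p = 1e-05, the smallest possible; adjusted over 2 relations 2e-05) and Pearson's r was 0.86 (p = 2e-05, adjusted 4e-05). Without chromosomes 7 and 2, which lie farthest from the median gene number, r was 0.94. The relation with span was rho = 0.72 (p = 0.00077, adjusted 0.00077) and r = 0.62 (p = 0.0044, adjusted 0.0044), and r was 0.57 without chromosomes 1 and 2. Whether the difference between the relations exceeds chance was not tested. Chromosome 15 had the most peaks per 100 genes among the autosomes, 31.3, and chromosome 7 the fewest, 16.9.

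Chromosome X held few Tle3 peaks for its size. Fewer genes on X do not account for it: X had 4.14 peaks per 100 protein-coding genes (2.96 to 5.63), below the 16.9 of the lowest autosome. A single X copy, which would halve the signal if the cells came from males, stays open. If every autosomal score were halved, a density equal to that of the autosomes would leave 84.0 peaks on X, against 40 (28.6 to 54.4) called, but the halving is an assumed profile and the sex of the animals is not used here. Lower mappability of X and a true lack of Tle3 on X may also contribute and were not tested. Beyond gene number and the assumed halving, no explanation was tested, and the design has no second group.

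Peaks lay close together more often than at random. Calls split from one broad region may add to this, as 189 of the 631 adjacent pairs within 10 kb (30.0%) were under 1 kb apart. Splits with gaps under 1 kb are not the whole cause. After merging at 1 kb, 16.4% of regions had a neighbour within 10 kb, against at most 5.86% at random. The median gap of the pairs was 2.79 kb, so this merging cannot tell whether calls split with wider gaps explain the rest. Dense megabase-scale regions are also not the whole cause, since placing each peak at random within its own 1 Mb tile gave at most 12.6%, against 22.2%. Variation in gene density below 1 Mb and clustered regulatory elements stay open and could not be separated without an annotation of the build.

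On chromosome 16, 69 of 170 peak midpoints (40.6%, 33.1 to 48.4%) lay within 1 kb of an end of a protein-coding gene of the GRCm38.p6 table, against 4.12% (1.67 to 8.30%) after a shift of 20 kb either way. The highest share on any other chromosome was 13.4%, on chromosome 19. A candidate explanation is that mm9 and GRCm38 share coordinates over part of chromosome 16, in which case many Tle3 peaks there would lie at gene ends. The loss of the match after a shift of 20 kb is in line with this, but the pattern was found and tested on the same peaks. Over the other 19 chromosomes the unshifted share was 7.07% (6.37 to 7.82%), against 6.10% and 5.88% after the shifts.

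Peaks with a neighbour within 10 kb had a median score of 70.88, against 68.28 for the 3996 isolated peaks, a difference of 2.60 (two-sided permutation p = 0.0175). The permutation treats peaks as independent, although those with a neighbour lie in groups, so this p may be too small. Whether scores within a group are alike was not tested. Peaks with a neighbour were also wider, with a median of 671 bp against 654 bp, and score rose with width. The hypothesis that clustered regions carry stronger peaks was therefore not settled, and the difference is small beside the distance between the quartiles of all scores, 56.7 and 99.2.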
